A study of Mus musculus with 2 samples.

How the data were processed

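Single-cell RNA was measured by 10x Genomics droplet sequencing in 2 libraries of mouse brain tumour with mutant IDH1, replicates 1 and 2, which form 1 group. Per the labels, the authors made the deposited count matrices with Cell Ranger 3.1, which aligned reads to mm10 with STAR, kept barcodes called as cells and counted UMIs per gene and barcode; the values are raw counts without normalization. The labels also name a combination of runs at equal depth, but the totals of the deposited matrices differ and their barcodes carry the suffix of single runs, so the counts were used as they are. The gene annotation was not stated. Coordinates were taken from GENCODE M21 (GRCm38, the same assembly as mm10), where 30934 of the 31053 gene identifiers were found. Reads of close paralogs are counted only where they align uniquely, so the level of a gene with similar copies is a lower limit.

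Cells were kept with at least 200 genes and at most 15 percent mitochondrial UMIs, and doublets called by scrublet (expected rate 0.04) were removed. Genes found in at least 3 cells were kept. Counts were scaled per cell and logged, 2000 variable features were chosen, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave the clusters (scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). The genes of the fixed lists were left out of the features, but related genes outside the lists, such as other interferon-induced genes, stayed in. Clusters were named by hand after clustering, from markers listed beforehand. Immune classes were named from the markers among the 10 leading genes, with at least 3 markers detected at 10 CPM or more. Glioma-like clusters were those where Sox2, Nes and Tnc were detected and no listed marker of another type led. Cluster 0 kept its number because microglia and macrophage markers both led, and clusters 12, 15 and 19 stayed unnamed because markers of different types were mixed or few. CPM is a gene's count over the UMI total of a class in a library, times 1000000. Means and SDs are over the 2 libraries, and binomial and counting intervals are exact at 95 percent. Intervals and floors cover counting error only. With 2 libraries no test between groups of samples was possible.

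For comparisons between classes, raw counts were summed per library and class with at least 20 cells in each library. The sums of 8 classes entered one edgeR 4.0.16 quasi-likelihood fit with TMM factors, filterByExpr and the library as a block (7 residual degrees of freedom), in R 4.3.3; the 7 glioma-like clusters entered another (6 degrees of freedom). A contrast sets a class against the mean of the log2 levels of the others, so its fold can differ from the ratio of the CPM means. Each class counts alike in that mean, and the fitted level of a gene in a class without counts of it depends on the prior count. A gene was called with a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1, and "rose", "fell", "higher" and "lower" are used for called genes and lists. With the library as a block, p-values measure only how the differences between classes vary from library to library. That spread may be technical or come from the sampling of cells, since the labels do not say that the libraries are separate animals. The p-values also take clusters found in the same cells as given, so they overstate how surely clusters differ.

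Gene lists, 21 with 320 genes of which 319 were measured, covered myeloid suppression, checkpoint ligands, colony-stimulating factors and receptors, inflammatory cytokines and chemokines, MHC class I and II presentation, interferon response, hypoxia and glycolysis, oxidative phosphorylation, reactive oxygen machinery, cell cycle, angiogenesis and matrix remodelling, dissociation stress, astrocyte-like, oligodendrocyte-progenitor-like, neural-progenitor-like and mesenchymal-like glioma states, T and NK effector genes, T cell exhaustion and regulation, DNA and histone methylation enzymes, and p53 and DNA damage response. The oligodendrocyte-progenitor-like list had fewer than 3 tested genes in every comparison and was not tested. Lists were tested with limma 3.58.1 camera, which asks whether the genes of a list rank higher or lower than the other genes. It was run with the preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, and p was adjusted over lists within a comparison. Unless a correlation is named, a list's p is the preset one. The limma test fry was run too: its directional p asks whether a list's genes move on balance one way and its mixed p whether they change in either direction, and neither compares them with other genes, so the text gives camera. Counts adjusted over the list alone correct for the genes of that list only.

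Lists, markers, comparisons, thresholds, the first set of alternatives and the rule for named genes were set before the data were examined. The rule names Csf3 and Csf3r in each comparison, of each list up to 2 called members with the largest absolute log2 fold change until 25 genes, taking the lists in order of their camera p, and the 3 largest rises and 3 largest falls among called genes with a mean of at least 50 CPM that were not features, markers or list members. Genes given as outside the lists are those of this last kind, so rankings among them leave out features, markers and genes of lower level. Other genes that are named, with a level or as members behind a small count, were chosen after their values were seen. A gene with 0 counts on one side is given as a bound against a floor of 3 counts, from counts pooled over the libraries and classes of each side. Fitted folds of such genes depend on the prior count and are not given. The comparison of mast cell or basophil-like cells was added after the data were seen.

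The alternatives were RLE size factors, the DESeq2 1.42.0 Wald test, no low-count filter, no replicate block, a fit of the compared classes alone, leaving out each library, doublets kept, at least 500 genes per cell, at most 10 percent mitochondrial UMIs, Leiden resolution 0.5 and 2 (the finer clustering), list genes allowed as features, an estimated inter-gene correlation, and cells thinned to 1000 UMIs. Each changed 1 choice, except that the re-clustered ones (doublets, both cell filters, both resolutions and the features) also took a minimum of 15 cells per library. Added after the data were seen were cluster 12 counted as glioma-like, barcodes without a Malat1 UMI left out, and that minimum.

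The libraries were compared by a chi-square statistic over genes with at least 20 counts, set against 100 random deals of the same cells to the libraries, and their makeup by 10000 permutations. The fits were tested on simulated data with the depths of these sums and 100 genes changed at each fold. Changed genes were drawn from those above 20 CPM, and all genes had the same dispersion. That dispersion was set at 0.05 and not estimated from these data. In the main fit the square root of the dispersion was 0.0684, which is a lower dispersion. Apart from the changed genes, all classes had the same mean profile, so differences in makeup between classes were not simulated. Recovery meant an adjusted p under 0.05 in the right direction, without the fold threshold of a call. By that measure 4-fold changes were recovered for 96 percent of genes in glioma-like against myeloid classes. It was 97 percent for cluster 0, 86 percent for dendritic-like and 41 percent for neutrophil-like cells. For 2-fold changes the values were 53, 36, 29 and 4 percent. Unchanged genes made up 3.25 to 4.26 percent of the genes under that adjusted p. At the simulated dispersion, a change of 2-fold in neutrophil-like cells was thus mostly not recovered. These percentages need not hold for the spread of the real sums. Left out were sequence variants, which the matrices do not hold, cell trajectories, and the comparisons whose classes had too few cells. Figures were drawn with matplotlib 3.10.9. Results for some of the genes tested are not reported here.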

Results

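Single-cell RNA counts were measured in a brain tumour of C57BL/6 mice that carries mutant IDH1 (mIDH1), taken at the symptomatic stage. The samples were 2 droplet libraries, replicates 1 and 2, and both belonged to the same group, so no other tumour or treatment could be compared. The labels did not state whether the libraries came from separate animals. Replicate 1 held 2704 barcodes with 63001350 unique molecular identifiers (UMIs) in total, and replicate 2 held 2266 barcodes with 58915133. Of these, 35.7% and 36.2% were removed, most for a high mitochondrial share (median of the removed barcodes, 86.6% and 85.3%). After removal of 11 and 3 doublets, 1729 cells with a median of 31951 UMIs remained in replicate 1, and 1443 cells with a median of 35758 in replicate 2. The title of the series concerns granulocyte colony-stimulating factor (G-CSF, gene Csf3) from mutant IDH1 glioma stem cells and the myeloid cells it acts on, and its design text concerns heterogeneity within the tumour. The comparisons were therefore made between classes of cells inside the same libraries, and every log2 fold change below is against the mean of the log2 levels of the other classes or clusters named. Bounds given as at least a fold are against their pooled counts.

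Glioma-like cells made up most of the cells kept, at 59.7% ± 1.66 (SD, n = 2 libraries, 1898 cells). In the re-clustered alternatives their share ran from 55.1% to 65.7%. Glioma-like cells were named for the stem and progenitor cell gene Sox2 (17.5 ± 1.16 CPM), the filament gene Nes (111 ± 2.72) and the matrix gene Tnc (43.5 ± 0.786). Of these, Sox2 had 0 counts in cluster 0 and in macrophage-like and neutrophil-like cells. The other listed glioma markers (Ptprz1, Olig1, Fabp7, Egfr, Bcan, Ncan and Cspg5) were under 10 CPM in each glioma-like cluster. Unnamed cluster 15 had 5 glioma markers detected, and unnamed clusters 12 and 19 had 3 each, so the name rests on few markers. Immune classes together made up 31.4% ± 0.841 (995 cells). Among them, the largest was cluster 0 (8.91% ± 1.22, 280 cells), whose leading genes included Apoe, C1qa, Cx3cr1, Trem2 and Csf1r. Cx3cr1 is a marker of microglia, the resident macrophages of the brain, but macrophage markers were more frequent among its leading genes, so the class was kept under its number. Macrophage-like cells followed at 6.28% ± 0.132, mast cell or basophil-like cells at 5.32% ± 0.570 and dendritic-like cells at 3.47% ± 0.00368. In some alternatives macrophage-like cells were fewer than mast cell or basophil-like cells, such as 5.11% against 5.37% with at least 500 genes per cell. Monocyte-like cells, led by Lyz2, Chil3 and Ly6c2, made up 2.81% ± 0.0461, and T-like cells made up 2.53% ± 0.144. Neutrophil-like cells, led by S100a8, S100a9 and Ngp, were 1.33% ± 0.0803 of all cells (22 and 20 cells) and 4.23% ± 0.142 of immune cells. B-like cells (0.775% ± 0.213, 25 cells) also had haemoglobin genes among their leading genes. Another 8.85% ± 0.816 of cells (279 cells) stayed unnamed. The class makeup of the libraries did not differ beyond the random dealing of cells (permutation test, p = 0.668).

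**Figure D1:**
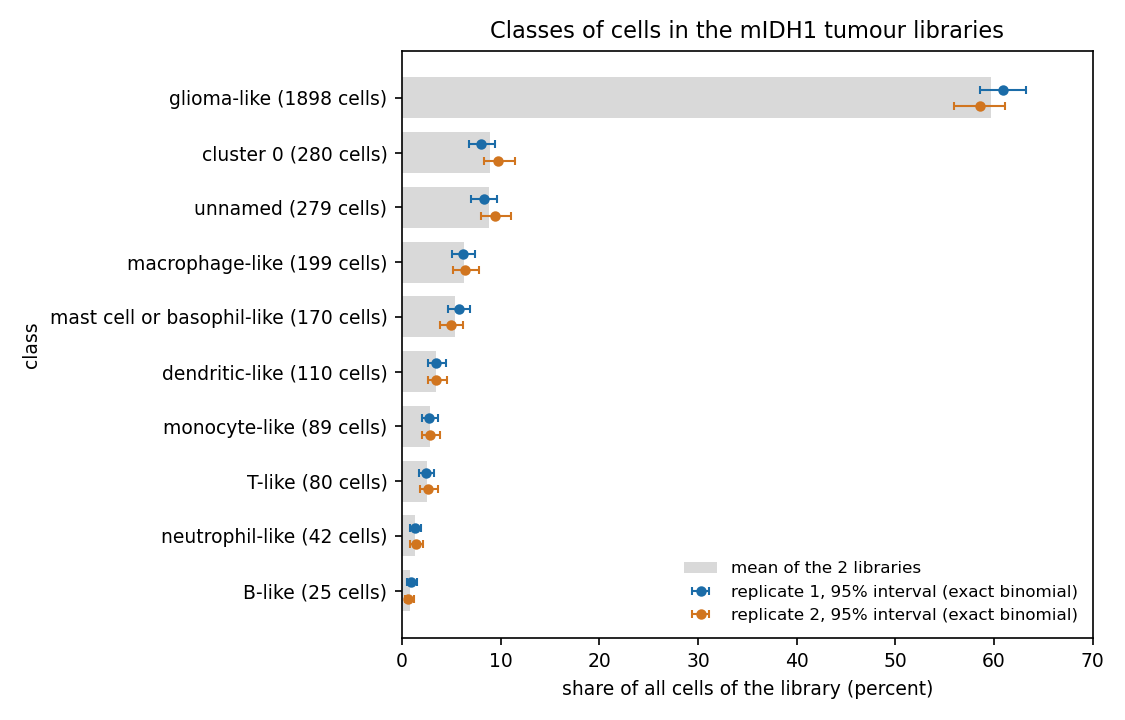
Share of each class among the cells of each library, in percent: points show replicates 1 and 2 with exact binomial intervals, and bars show the mean of both. The glioma-like points lie at 60.9% and 58.6%, and no other class exceeds 9.77% in either library.

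Of the 199 macrophage-like barcodes, 126 (63.3%) held no UMI of Malat1, a nuclear RNA found at high level in most cells. These 126 barcodes had a median of 4380 UMIs against 10298 in the 73 others, and 1.48 CPM of the nuclear RNA Xist against 1313. Their levels of Apoe, a lipid carrier of macrophages, were 44877 against 32467 CPM. No Malat1 UMI was found either in 38 of the 112 barcodes of unnamed cluster 15 and in 11 of the 23 of unnamed cluster 19, against 10 in the other 17 clusters together. With all 185 such barcodes left out, the macrophage-like share was 2.39%. Malat1 and Xist were chosen after their values were seen.

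Csf3 (ENSMUSG00000038067, chromosome 11, 98701263 to 98703629, plus strand, GRCm38), which encodes G-CSF, was counted in glioma-like cells at 8.23 ± 1.10 CPM (SD, n = 2; 482 and 368 counts). It had 0 counts in every immune class and 24 in the unnamed cells. A UMI of Csf3 was found in 316 of 1898 glioma-like cells, or 16.6% (95% exact binomial interval 15 to 18.4), at a median of 46422 UMIs per cell. It was found in 0 of 280 cells of cluster 0 at a median of 10438 UMIs, which by a floor of 3 cells allows a share of cells with a UMI of up to 1.07%, and does not limit cells that express it at a lower level. With each cell thinned to 1000 UMIs, the glioma-like share was 0.738%, so a difference in shares was not detectable at that depth. Csf3r (ENSMUSG00000028859, chromosome 4, 126024550 to 126044440, plus strand), the G-CSF receptor, was highest in neutrophil-like cells at 1463 ± 105 CPM. It stood at 164 ± 1.18 in cluster 0, 78.8 ± 3.37 in monocyte-like, 61.1 ± 7.73 in macrophage-like and 0.157 ± 0.0639 in glioma-like cells. Of the neutrophil-like cells, 88.1% held a Csf3r UMI (median 2369.5 UMIs), against 0.421% of glioma-like cells (median 46422 UMIs).

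The following genes, named in work on this tumour type or marking its sex chromosomes, were chosen after their values were seen. Nras (ENSMUSG00000027852, chromosome 3, 103058285 to 103067914), a growth-signalling GTPase, stood at 2865 ± 364 CPM in glioma-like cells, and at between 51.4 ± 31.7 in neutrophil-like and 260 ± 6.90 in macrophage-like cells. The tumour suppressor Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873) was at 12.9 ± 0.503 CPM in glioma-like cells and 69.0 ± 1.77 in cluster 0. Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653), a cell cycle inhibitor gene, was at 372 ± 6.40 against 7.59 ± 1.92. Idh1 (ENSMUSG00000025950, chromosome 1, 65158616 to 65186500), the gene mutated in this tumour type, was at 72.7 ± 3.47 in glioma-like cells, and the counts do not separate its alleles. Il34, a ligand of the receptor Csf1r, was at 12.5 ± 0.405 CPM in glioma-like cells, with 1 count in all immune classes together. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), made from the inactive X chromosome, was at 4.87 ± 1.71 CPM in glioma-like cells against 1486 ± 79.1 in cluster 0 and 125 ± 32.7 in neutrophil-like cells.

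**Figure D2:**
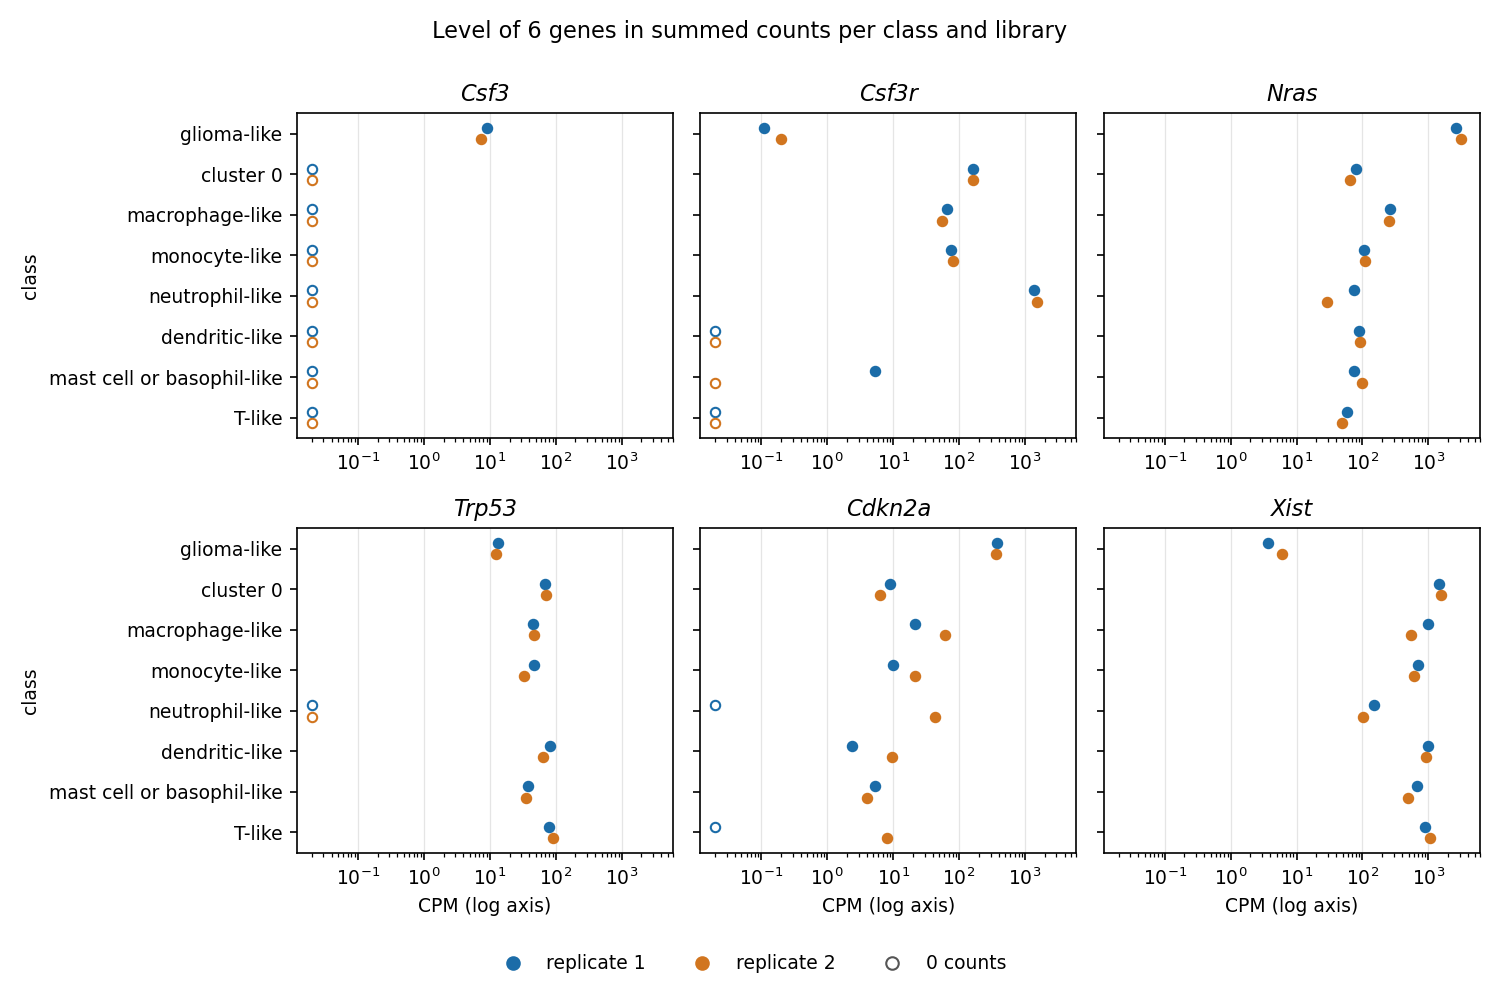
Level of 6 genes in CPM on a log axis, per class, with 1 point for each library; open points at the left edge mark 0 counts and have no level. Unnamed and B-like cells are not drawn. Among the 8 classes drawn, Csf3 has filled points only in glioma-like cells (mean 8.23 CPM), where Xist is lowest (mean 4.87 CPM) and Nras highest (mean 2865 CPM).

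The comparison of glioma-like cells with the 4 myeloid classes (cluster 0, monocyte-like, macrophage-like and neutrophil-like) asked which signals the tumour cells and the myeloid cells of this tumour each expressed. Csf3 was at least 16.8-fold higher in glioma-like cells, against a floor of 3 counts over the 4 classes. It was not tested, because the low-count filter takes its CPM cutoff from the median size of the sums. The Csf3 level lay under that cutoff, although both libraries held many Csf3 counts in the deep glioma-like sums. Other genes of such a level found only in glioma-like cells were left out alike. Csf3r fell, from 442 ± 24.9 to 0.157 ± 0.0639 CPM (SD, n = 2). The edgeR log2 fold change was -9.99 ± 0.21 (SE, adjusted p = 4.06e-22). Among colony-stimulating factors and receptors, 1 of 10 tested members rose (Kitl, the ligand of Kit) and 6 fell, among them Csf1r, the receptor of macrophage growth factors (-10.76 ± 0.75). The list fell by camera (adjusted p = 0.00654, and 0.0628 with an estimated correlation). Csf3 belongs to this list but was left out by the filter, so the fall does not cover it. The list joins ligands and receptors, so its fall is not one of the ligands as a set. Cell cycle genes rose: 19 of 20 were higher and 0 lower, such as Ube2c, a mitotic ubiquitin enzyme (6.12 ± 0.46; 307 ± 22.6 against 23.1 ± 2.43 CPM), and the kinase Cdk1 (6.03 ± 0.38). The list's adjusted p was 4.14e-05, and 0.185 with an estimated correlation. All 4 tested neural-progenitor-like genes rose, with Sox11 (8.43 ± 0.53) and the neuronal tubulin Tubb3 (8.13 ± 0.43) the furthest (adjusted p = 0.00654, and 0.0754 with an estimated correlation). Of the mesenchymal-like genes 8 of 11 rose, such as Emp1 (6.89 ± 0.25), and 2 fell, such as the matrix protein Tgfbi (-5.99 ± 0.34; list adjusted p = 0.0236, and 0.283 with an estimated correlation).

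Inflammatory cytokines and chemokines were lower in glioma-like cells for 17 of 23 genes and higher for 0. Il1b, an inflammatory cytokine, stood at 0.330 ± 0.307 against 2107 ± 534 CPM (-10.94 ± 0.56), and the list fell (adjusted p = 1.02e-07, and 0.0252 with an estimated correlation). The myeloid suppression list also fell under both correlations (0.000291 and 0.0359), with 12 of 15 lower, such as Cd84 and Wfdc17, and Ptges, a prostaglandin synthase, higher. So did reactive oxygen machinery (0.000339 and 0.0374), with 10 of 13 lower, among them the phagocyte oxidase subunits Cybb (-11.88 ± 0.35) and Ncf4 (-11.83 ± 0.29). The T cell exhaustion list fell by the test (0.000339 and 0.0374), but 1 of 10 genes was called, the ectonucleotidase Entpd1 (-10.22 ± 0.36), which myeloid cells also express. Both MHC lists fell, though neither stayed called with an estimated correlation: 7 of 11 MHC class II genes fell, such as the protease Ctss (1.62 ± 0.0592 against 5919 ± 86.9 CPM). Likewise, 8 of 13 MHC class I genes fell, such as the proteasome subunit Psmb9 (57.7 ± 3.79 against 319 ± 17.6 CPM). Their adjusted p values were 2.26e-05 and 0.00159, and 0.128 and 0.126 with an estimated correlation. Checkpoint ligands fell in 7 of 10, such as Sirpa (-7.83 ± 0.26), with Pvr higher (adjusted p = 0.00368, and 0.0628 with an estimated correlation). Interferon response genes fell in 10 of 20, while Ifi44 rose (3.90 ± 0.64; list adjusted p = 0.00459, and 0.202 with an estimated correlation). Dissociation stress genes fell in 8 of 15, such as Dusp1 and Zfp36, while the chaperones Hspa1b and Hsp90aa1 rose (0.0373, and 0.256 with an estimated correlation). The T and NK effector list was called lower (0.00159, and 0.168 with an estimated correlation), though 0 of 9 genes were called and its median (0.60) and mean (-1.07) differed in sign.

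The other 6 lists were not called in this comparison. In oxidative phosphorylation 4 of 18 genes rose, such as Atp5b, a subunit of the ATP synthase (1.44 ± 0.15; list adjusted p = 0.0787 by camera). In angiogenesis and matrix remodelling 4 of 16 rose, among them Vegfa and Fn1, and 4 fell (list 0.26). Of 17 methylation enzymes 7 rose, among them Dnmt1, Ezh2 and Idh1, while Tet2 and Dnmt3a fell. Of 12 p53 response genes 5 rose, among them Cdkn2a and Atrx, and 2 fell, and of 20 hypoxia genes 2 rose and 3 fell. Each of these 3 lists had an adjusted p of 0.548 by camera. Atrx stood at 125 ± 6.26 CPM in glioma-like cells and 110 ± 3.39 in cluster 0, so its call rests on the other myeloid classes. It was higher in T-like (174 ± 37.5 CPM) and dendritic-like cells (208 ± 22.0), which were not part of this comparison. In the astrocyte-like state 2 of 6 rose and 3 fell (0.686). The hypoxia list had a median of 0.39 and a mean of -0.32, and the astrocyte-like list a median of -0.72 and a mean of 0.05. Adjusted over the list alone, the counts were the same except for checkpoint ligands (2 rose and 7 fell). Outside the lists, features and markers, the largest rises with full counts were Fermt1 (9.37 ± 0.44), an integrin-binding protein, and Nrn1 (9.04 ± 0.53). The largest falls included the immune adaptors Tyrobp (-11.56 ± 0.36) and Fcer1g (-11.22 ± 0.36). In all, 4225 of 8213 genes were called, 2714 higher and 1511 lower, against a median shift of 0.44 over all genes. The glioma-like class held 102871956 UMIs and the 4 myeloid classes 6099549, so low levels are better resolved in the former. The neutrophil-like class, with 136602 UMIs and 2165 genes at 0 counts, weighed as much in the mean as each other myeloid class. For genes without counts in it, the folds above depend in part on the prior count and can exceed the ratio of the CPM means.

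Neutrophil-like cells were compared with the monocyte-like and macrophage-like classes, since neutrophils are the main cells that G-CSF acts on. Csf3r was at 1463 ± 105 against 70 ± 2.18 CPM (SD, n = 2), and Csf3 had 0 counts in both. The edgeR log2 change of Csf3r was 4.08 ± 0.18 (SE, adjusted p = 1.4e-14). Chemokines went both ways: 7 of 23 genes of the cytokine list rose, among them the neutrophil attractant Cxcl3 (6.41 ± 0.26; 1930 ± 801 against 31.4 ± 8.01 CPM), and 8 fell. Of the myeloid suppression list 4 of 15 rose, among them Arg2, an arginase (5.0 ± 0.59; 329 ± 6.10 against 14.8 ± 8.57 CPM), and the lectin receptor Clec4e (3.78 ± 0.36), while 3 fell. MHC class II genes fell in 10 of 11: H2-DMb1 and the co-stimulator Cd86 had 0 counts and were at least 14.1-fold and at least 11.6-fold lower, against a floor of 3 counts over the class. The list's adjusted p was 0.000138, and 0.267 with an estimated correlation. MHC class I genes fell in 10 of 13, such as the chaperone Calr (-2.66 ± 0.33; list adjusted p = 3.92e-05, and 0.144 with an estimated correlation). Respiratory chain genes fell in 15 of 18, such as Sdhb (-3.07 ± 0.50; 0.000305, and 0.432 with an estimated correlation). Dissociation stress genes rose in 7 of 15, such as Dusp1 (3.65 ± 0.23) and Ier3 (2.38 ± 0.25), and 1 fell (4.18e-05, and 0.144 with an estimated correlation). The T and NK effector list was called higher (4.18e-05, and 0.234 with an estimated correlation) with 0 of 9 genes called, a median of 0.00 and a mean of -0.64.

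The other 15 lists were not called. Colony-stimulating factors and receptors were at an adjusted p of 0.0601 (3 of 10 rose: Csf1, Csf3r and Cxcr4; Csf1r fell by 3.40 ± 0.54), with a test direction up and a median of -0.86. The mesenchymal-like list was also at 0.0601, with test direction up, median -0.49 and mean -0.32. Of its 11 genes 5 rose and 2 fell, and the risers included the S100 protein S100a11 (3.73 ± 0.21) and Anxa1 (4.03 ± 0.25), an inhibitor of inflammation. The rest lay between 0.134 for myeloid suppression and 0.903 for hypoxia. Among them, the checkpoint ligand Cd274 and the receptor Siglece rose, 3 interferon response genes rose and 5 fell of 20, and 3 cell cycle genes fell and 1 rose. Lists tested upward with a negative median were neural-progenitor-like, cytokines, T cell exhaustion, p53 response, reactive oxygen machinery, checkpoint ligands, methylation enzymes and hypoxia, and myeloid suppression had a median of 0.19 and a mean of -0.57. Adjusted over the list alone, 11 MHC class I genes, 10 cytokines, 7 interferon response genes and 3 checkpoint ligands fell, 3 mesenchymal-like and 3 p53 response genes fell, 4 interferon response genes and 1 MHC class II gene rose, and 1 neural-progenitor-like gene fell. Outside the lists, features and markers, Mgst2 (5.20 ± 0.76), the glucokinase Adpgk (4.38 ± 0.45) and Rnd1 (4.37 ± 0.71) rose the furthest. Fkbp2 was at least 8.67-fold, Sdf2l1 at least 6.29-fold and Plxnb2 at least 6.01-fold lower.

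Of 8213 genes, 1801 were called for neutrophil-like cells, 464 higher and 1337 lower, around a median of -1.25 over all genes. The class held 136602 UMIs, 2165 genes had 0 counts in it, and 376 of the lower calls (28.1%) were such genes; with them at their bound the median was -0.28. With RLE size factors the median was -0.78 and 620 genes were higher and 675 lower, with 1139 calls shared. With DESeq2 710 were higher and 570 lower, with 981 shared, so the balance of higher and lower genes here rests on the scaling and the test.

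Cluster 0 was compared with the monocyte-like and macrophage-like classes, and macrophage markers were among the leading genes of both cluster 0 and the macrophage-like class. Csf3r rose, at 164 ± 1.18 against 70 ± 2.18 CPM (SD, n = 2). Its edgeR log2 change was 1.16 ± 0.15 (SE, adjusted p = 2.41e-06). All 11 mesenchymal-like genes fell, among them the intermediate filament gene Vim (96.1 ± 50.9 against 1474 ± 233 CPM, -3.82 ± 0.27) and S100a6 (-3.88 ± 0.26; list adjusted p = 4.78e-15, and 0.0366 with an estimated correlation). Hypoxia and glycolysis genes fell in 9 of 20, such as Ndrg1 (-4.12 ± 0.40) and the glycolytic enzyme Pfkp (-2.53 ± 0.25; list 1.42e-10, and 0.0918 with an estimated correlation). The myeloid suppression list fell (0.00177, and 0.0543 with an estimated correlation) with 7 of 15 lower and the protease Ctsd higher. The arginase Arg1 was at 4.43 ± 1.75 against 547 ± 88.4 CPM (-6.86 ± 0.55), and the arginine transporter Slc7a2 was at least 21.0-fold lower at 0 counts. Cytokines and chemokines fell in 10 of 23 with Ccl8 higher (0.0199, and 0.134 with an estimated correlation). Reactive oxygen genes fell in 5 of 13: Cybb, Ncf4, Gpx1, Sod2 (-1.52 ± 0.21) and Prdx5 (-1.33 ± 0.20; list 0.000742, and 0.0543 with an estimated correlation). The Sod2 call was lost in 6 alternatives, with log2 values from -0.97 to -0.76, and that of Prdx5 in 2. Among interferon genes 4 of 20 fell, such as Ifitm3 (-1.53 ± 0.23; list 0.00636, and 0.29 with an estimated correlation); Rsad2 (-1.47 ± 0.34) was called too but lay between 0.10 and 0.38 in 5 re-clustered or filtered alternatives.

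Neural-progenitor-like genes fell in 3 of 4 (0.0166, and 0.119 with an estimated correlation): Sox4, Cd24a and Tubb3, of which Cd24a and Tubb3 lost the call at the finer clustering. MHC class II genes fell in 2 of 11, Cd80 and Cd40, each with a call lost in 1 alternative (list 0.0203, and 0.462 with an estimated correlation). Oxidative phosphorylation fell with 0 of 18 genes called (0.0036, and 0.486 with an estimated correlation). The T cell exhaustion list rose (0.0322, and 0.134 with an estimated correlation) with Pdcd1, Lag3, Ikzf2 and Icos higher, receptors and a transcription factor also known in other leukocytes (Icos lost its call in 2 alternatives), and Tnfrsf9 lower (-2.44 ± 0.52). The T cell markers Cd3d (16.7 ± 2.83 CPM) and Cd3g (18.2 ± 3.98) were also counted in cluster 0, against 0 counts in the monocyte-like and macrophage-like classes. The other 10 lists were not called, with adjusted p values from 0.115 for cell cycle to 0.933 for the astrocyte-like and the T and NK effector lists. Among them, angiogenesis genes rose in 2 and fell in 7 of 16, such as the growth factor Vegfa (-3.50 ± 0.43), and Csf1r rose beside Csf3r. For colony-stimulating factors and receptors the median (-0.26) and the test direction (up) differed in sign, and for methylation enzymes the median (0.09) and the mean (-0.01) did. Adjusted over the list alone, T cell exhaustion had 5 rises, angiogenesis 8 falls, checkpoint ligands 2 falls and cell cycle 0 rises. Outside the lists the neuron navigators Nav3 (2.44 ± 0.19) and Nav2 (2.30 ± 0.22) and the adhesion receptor Adgrg1 (2.14 ± 0.20) rose. Ahnak (-4.58 ± 0.32), Capg (-2.75 ± 0.24) and Tmsb10 (-2.53 ± 0.22), which bind or organise actin or membrane, fell.

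For cluster 0, 1008 of 8213 genes were called, 479 higher and 529 lower (median 0.03); with RLE size factors 631 were higher and 447 lower (median 0.15), and at the finer clustering 78.3% of 1219 calls were higher, with 624 shared. Without the barcodes that lacked Malat1, 1003 genes were called and 885 of the calls were shared.

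Dendritic-like cells were compared with the same monocyte-like and macrophage-like classes. Csf3r had 0 counts in them and was at least 19-fold lower (against 70 ± 2.18 CPM, n = 2), and Csf1r fell by 4.40 ± 0.41. The myeloid suppression list fell with 11 of 15 lower (adjusted p = 7.13e-08, and 0.0044 with an estimated correlation): the nitric oxide synthase Nos2 and Clec4e had 0 counts and were at least 16-fold and at least 12.9-fold lower. Angiogenesis and matrix genes fell in 12 of 16 (7.13e-08, and 0.0044 with an estimated correlation), with the proteases Mmp8 and Plau at 0 counts, at least 5.32-fold and at least 4.36-fold lower. Hypoxia and glycolysis genes fell in 14 of 20, such as Bnip3 (-3.92 ± 0.40) and the lactate transporter Slc16a3 (-3.80 ± 0.31), and Ndrg1 rose (list 7.19e-08, and 0.188 with an estimated correlation). Interferon genes fell in 7 of 20, such as Ifit3 (13.1 ± 15.1 against 150 ± 4.01 CPM; list 0.00232, and 0.26 with an estimated correlation). Reactive oxygen genes fell in 6 of 13, such as Prdx5 (-3.10 ± 0.24) and Cybb (-2.68 ± 0.23; 0.00275, and 0.0999 with an estimated correlation). Cytokines and chemokines fell in 12 of 23, such as Ccl7 (at least 53.2-fold lower) and Il1a (at least 20-fold lower). They rose in 4, Il12b, Ccl5 and the T cell attractants Ccl17 and Ccl22 (list 0.0241, and 0.215 with an estimated correlation). The T and NK effector list rose (0.0285, and 0.347 with an estimated correlation) with Klrd1 (at least 134-fold higher), Gzmb (7.39 ± 1.38) and Nkg7 higher of 9. These are receptors and granule genes of killer cells, and the class also held the T cell marker Trac (10.7 ± 8.42 CPM, against 0 counts in the monocyte-like and macrophage-like classes). In cluster 16, which is part of the class, 5 T cell markers were detected, against 1 each in those 2 classes, and Cd7 was among its leading genes. Which cells of the class expressed these genes was not tested. The calls of Klrd1 and Gzmb were lost in 2 alternatives and 1. Oxidative phosphorylation fell with 1 of 18 genes called, Uqcrq (-1.04 ± 0.21, lost in 4 alternatives; list 0.0241, and 0.591 with an estimated correlation).

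The other 12 lists were not called for dendritic-like cells, with adjusted p values from 0.0522 for dissociation stress to 0.993 for the astrocyte-like state. MHC class II genes, the mark of dendritic cells, rose in 2 of 11, the regulator Ciita and the co-stimulator Cd80, and Ctss fell (list 0.643). T cell exhaustion genes rose in 6 and fell in 3 of 10 (list 0.286), checkpoint ligands rose in 1 and fell in 5 of 10 (list 0.537), and 3 methylation enzymes rose, among them the demethylase Kdm4a (2.38 ± 0.32; list 0.229). Tgfbi of the mesenchymal-like list fell (-3.57 ± 0.38; list 0.286). The astrocyte-like list was tested upward with a median of -0.75, and MHC class II with a median of 0.00 and a mean of 0.16. Adjusted over the list alone, 14 angiogenesis genes and 0 cell cycle genes fell and 2 checkpoint ligands rose. Outside the lists, features and markers, Spint2 (5.15 ± 0.33), a protease inhibitor, Grasp (5.09 ± 0.30) and Gypc (4.93 ± 0.41) rose the furthest, and Syngr1 was at least 72.0-fold lower. In all, 1905 of 8213 genes were called, 892 higher and 1013 lower (median -0.01). At the finer clustering 1108 were higher and 838 lower, and at resolution 0.5 1083 and 1442, with 18 calls opposite to the main ones, so which side is larger depends on the setting. Without the barcodes that lacked Malat1, 1688 of the calls were shared.

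The glioma-like cells formed 7 clusters, each compared with the mean of the other 6, which addresses heterogeneity within the tumour cells. Cluster 6 held 22.3% ± 3.32 of them (SD, n = 2), cluster 8 held 16.4% ± 2.31 and cluster 5 15.6% ± 1.52. Cluster 1 held 15.1% ± 0.403, cluster 9 14.5% ± 0.0857, cluster 18 8.55% ± 0.132 and cluster 7 7.55% ± 1.14. Csf3 rose in cluster 1, at 19.4 ± 3.92 against 6.94 ± 0.773 CPM in the others. The edgeR log2 change was 1.73 ± 0.18 (SE, adjusted p = 6.66e-08). It was not called in cluster 8 (0.31 ± 0.19), cluster 5 (-0.11 ± 0.19), cluster 7 (-0.30 ± 0.27), cluster 18 (-0.37 ± 0.25) or cluster 9 (-0.48 ± 0.20). In cluster 6 it was at -0.78 ± 0.20 (edgeR adjusted p = 0.0064, but under the fold threshold); with at least 500 genes per cell it was called at -1.38, and at the finer clustering at -1.44. Csf3r had 16 counts in all glioma-like cells and was not tested. Of 21 lists, 19 had at least 3 genes tested here. Since every cluster is part of the mean for the other clusters, the log2 changes of a gene balance out over the 7 comparisons. A strong rise in some clusters therefore goes with falls in others, and these are not separate results.

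**Figure D3:**
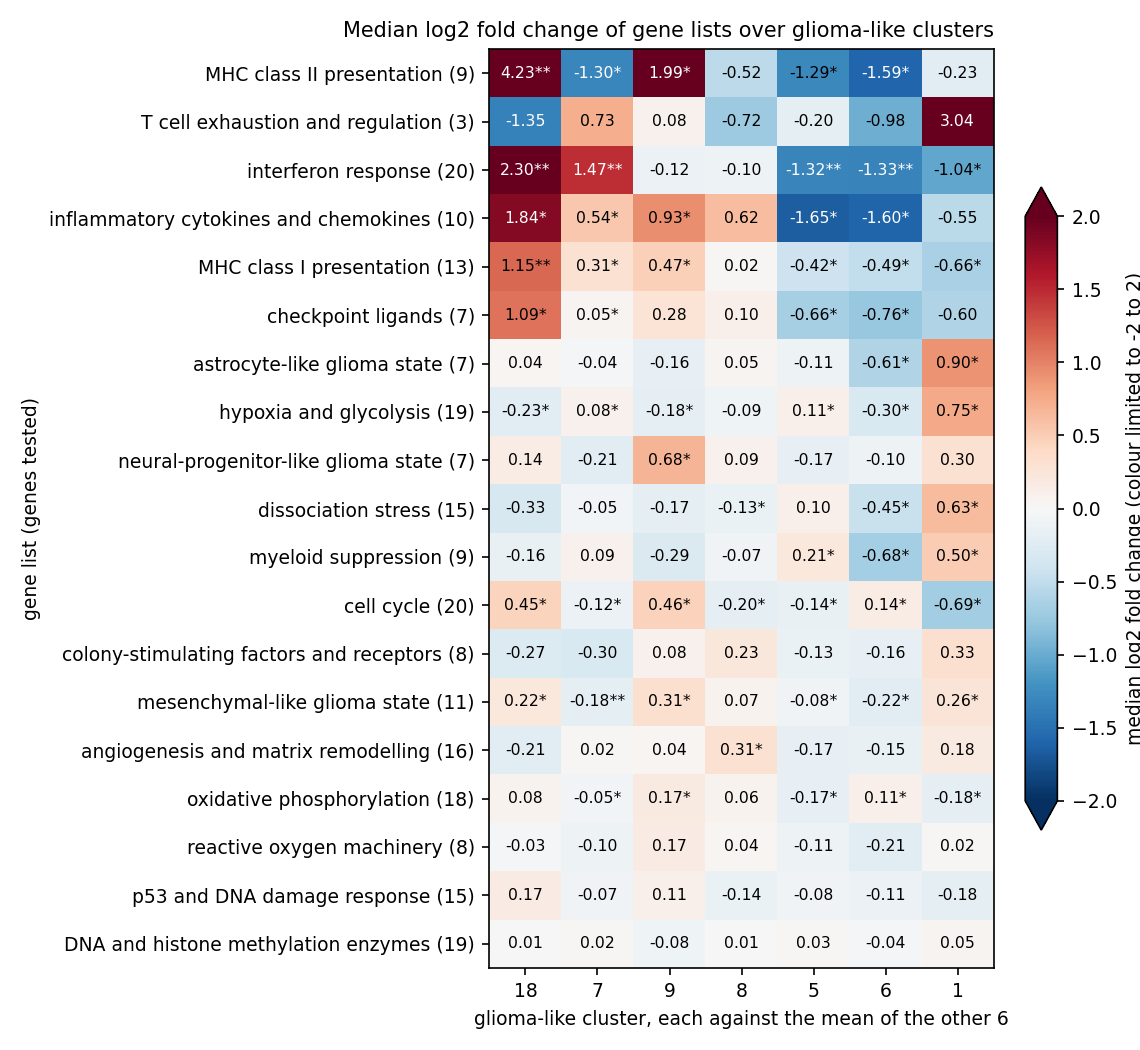
Median log2 fold change of each gene list in each glioma-like cluster against the other 6; 1 star marks lists called by camera, and a pair of stars those also called with an estimated correlation. The interferon response row runs from 2.30 in cluster 18 and 1.47 in cluster 7 to -1.32 in cluster 5 and -1.33 in cluster 6, all 4 with a pair of stars.

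Cluster 18 stood out by interferon and antigen presentation genes. List genes were no clustering features, but related genes were, such as Iigp1, Gbp4 and Cmpk2, which were among its leading genes. Oasl1 and Mndal, among the leading genes of cluster 7, were features too, as were the class II genes H2-DMb2 and H2-Eb2. The clusters were thus formed in part on these programmes, so the list p values of clusters 18 and 7 are no independent evidence. Interferon response genes rose in 17 of 20, such as the antiviral genes Mx1 (5.89 ± 0.17) and Ifit2 (124 ± 32.4 against 6.15 ± 0.348 CPM), and the list rose (adjusted p = 5.78e-43, and 0.00887 with an estimated correlation). MHC class II genes rose in 7 of 9, such as their master regulator Ciita (5.58 ± 0.50) and H2-Eb1 (4.70 ± 0.26; list 2.03e-10 and 0.00887). MHC class I genes rose in 7 of 13, such as Psmb9 (2.18 ± 0.07) and the peptide transporter Tap2 (1.94 ± 0.09; list 3.01e-18 and 0.0384). Chemokines rose in 6 of 10, with Cxcl10, a T cell attractant, at 1082 ± 20 against 58.6 ± 8.80 CPM and the monocyte attractant Ccl2 at 4.39 ± 0.14 (4.25e-05, and 0.0658 with an estimated correlation). Checkpoint ligands rose in 4 of 7, with Cd274, which encodes PD-L1, at 43.6 ± 9.83 against 8.08 ± 0.857 CPM, and Lgals9 at 2.65 ± 0.13 (0.00049, and 0.103 with an estimated correlation). Cell cycle rose with 0 of 20 called (3.18e-09, and 0.228 with an estimated correlation). Hypoxia fell with Ndrg1 called of 19 (1.34e-07, and 0.228 with an estimated correlation) and mesenchymal-like rose with 0 of 11 called (0.0486, and 0.249 with an estimated correlation). The enzyme Ido1 (3.65 ± 0.48) and Hopx (2.70 ± 0.20) rose, and Csf2, which encodes GM-CSF (-2.29 ± 0.56), and the prostaglandin synthase Ptgs2 (-1.85 ± 0.16) fell, in lists that were not called. Of 11525 genes, 542 were called, 422 higher and 120 lower. Outside the lists, features and markers, the interferon-induced GTPases Gbp3 (2.70 ± 0.09) and Irgm1 (2.33 ± 0.05) and Phf11d (2.72 ± 0.10) were the largest rises. Phlda2 (-1.63 ± 0.10) and Jag1 (-1.43 ± 0.12) were among the largest falls.

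Cluster 7 shared the interferon side without the class II side: interferon genes rose in 13 of 20, such as Rsad2 (2.96 ± 0.37), and the list rose (1.05e-74, and 0.00242 with an estimated correlation). MHC class II fell in 2 of 9, H2-Aa (1 count) and Cd74 (0.00354, and 0.155 with an estimated correlation), but both calls were lost with DESeq2, with doublets kept and at the finer clustering, where Cd74 was 0.32. The mesenchymal-like list fell with 0 of 11 called (2.85e-12, and 0.0125 with an estimated correlation). MHC class I rose with 0 of 13 called (1.94e-12, and 0.0956 with an estimated correlation), and so did hypoxia with 0 of 19 (0.00114, and 0.324 with an estimated correlation; median 0.08, mean -0.04). Checkpoint ligands (Lgals9 at 1.26 ± 0.17, lost at the finer clustering; 0.00402, and 0.222 with an estimated correlation) and chemokines (Cxcl10 at 2.58 ± 0.17, lost with doublets kept; 0.00633, and 0.191 with an estimated correlation) rose with 1 gene each. Cell cycle (4.8e-05, and 0.324 with an estimated correlation) and oxidative phosphorylation (0.00394, and 0.233 with an estimated correlation) fell with 0 genes called. In all, 83 genes were called, 74 higher, among them Phf11d (1.64 ± 0.12), Gbp3 (1.35 ± 0.11) and the DNA sensor family gene Ifi204 (1.28 ± 0.10). With doublets kept, 174 were called and 41.4% of them were higher.

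Cluster 9 was higher in MHC class II genes, 7 of 9, such as H2-Aa (2.60 ± 0.26) and Ciita (2.91 ± 0.62, but 0.94 without replicate 1; list adjusted p = 2.55e-05, and 0.0877 with an estimated correlation). Cluster 9 also held more Xist, at 23.4 ± 13.6 CPM against at most 3.94 ± 5.57 in the other 6 clusters, with its 423 UMIs in 15 cells. The receptor subunit Csf2rb had 22 counts in it (21 in replicate 1), against at most 4 in the others. The cluster was also higher in 2 of 13 MHC class I genes, the immunoproteasome subunits Psmb9 (1.32 ± 0.07) and Psmb10 (1.25 ± 0.06; 8.02e-09, and 0.126 with an estimated correlation). Chemokines rose in 5 of 10, such as Cxcl9, induced by interferon gamma (3.78 ± 0.46; 0.0144, and 0.144 with an estimated correlation). Interferon response as a list was not called (0.194; 3 rose, such as Gbp2 at 2.21 ± 0.06, and 1 fell of 20; median -0.12, mean 0.02). The cell cycle list rose with Rrm2 called of 20 (1.07e-13, and 0.126 with an estimated correlation). So did neural-progenitor-like genes with Stmn2, Dlx1 and Dlx2 of 7 (0.0195, and 0.126 with an estimated correlation). The calls of Rrm2 and Dlx2 were lost in 1 alternative each and that of Stmn2 in 3. Oxidative phosphorylation (2.66e-06, and 0.126 with an estimated correlation) and mesenchymal-like genes (4.23e-06, and 0.0877 with an estimated correlation) rose and hypoxia fell (9.13e-07, and 0.202 with an estimated correlation), each with 0 genes called. Of 253 called genes 187 were higher, with Irgm1 (1.39 ± 0.05), Gbp3 (1.37 ± 0.09) and Fdps, an enzyme of isoprenoid synthesis (1.32 ± 0.07), the largest rises outside the lists, features and markers. DESeq2 called 154 genes and the finer clustering 436.

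In clusters 5 and 6, each set against the other clusters, the interferon, MHC, chemokine and checkpoint ligand lists fell, while hypoxia, myeloid suppression, cell cycle and oxidative phosphorylation went opposite ways. With an estimated correlation only the interferon list stayed called in either cluster. Interferon response genes fell in 14 of 20 in each. In cluster 5 Ifit3 was at 6.33 ± 3.01 against 128 ± 25.7 CPM (list adjusted p = 6.46e-33, and 0.024 with an estimated correlation), and in cluster 6 Rsad2 fell by 3.37 ± 0.64 (1.16e-25, and 0.0451 with an estimated correlation). MHC class I fell in 4 of 13 in cluster 5, such as Psmb9 (-1.47 ± 0.10) and Psmb8 (-1.22 ± 0.09; 1.02e-17, and 0.0601 with an estimated correlation). It fell in 2 of 13 in cluster 6, Psmb9 (-1.52 ± 0.10) and Tap1 (-1.04 ± 0.07; 4.95e-13, and 0.0819 with an estimated correlation). Chemokines fell in 5 of 10 in cluster 5, with Ccl2 at -3.22 ± 0.32 (0.000267, and 0.0664 with an estimated correlation). In cluster 6 they fell in 2 of 10, with Ccl2 at -4.37 ± 0.34, and Cxcl10 was at 4.58 ± 0.108 against 238 ± 12.1 CPM (0.00237, and 0.0933 with an estimated correlation). MHC class II fell in 2 of 9 genes of cluster 5, such as H2-Ab1 (-2.15 ± 0.47; 0.00843, and 0.083 with an estimated correlation). In cluster 6 it fell in 5 of 9, such as Cd74 (-2.41 ± 0.25; 0.00307, and 0.0933 with an estimated correlation). Checkpoint ligands fell in 2 of 7 in each, Cd274 and Lgals9 (Lgals9 at -1.37 ± 0.18 and -1.73 ± 0.19; 0.016 and 0.00307, and 0.235 and 0.146 with an estimated correlation). The Cd274 call of cluster 5 was lost with doublets kept. In cluster 5, oxidative phosphorylation (1.44e-07, and 0.0664 with an estimated correlation), cell cycle (9.44e-05, and 0.35 with an estimated correlation) and mesenchymal-like genes (0.00991, and 0.18 with an estimated correlation) fell with 0 genes called. There, hypoxia (0.00567, and 0.426 with an estimated correlation) and myeloid suppression (0.0482, and 0.18 with an estimated correlation; median 0.21, mean -0.51) rose with 0 genes called. In cluster 6, hypoxia (3.84e-07, and 0.17 with an estimated correlation) and mesenchymal-like genes (8.98e-06, and 0.0819 with an estimated correlation) fell with 0 genes called. With 1 gene each, dissociation stress (Hspa1b at -1.91 ± 0.30; 0.00115, and 0.17 with an estimated correlation), astrocyte-like genes (Hopx at -1.15 ± 0.28; 0.00307, and 0.0819 with an estimated correlation) and myeloid suppression (Ido1, lost in 3 alternatives; 0.00392, and 0.103 with an estimated correlation) fell too. Cell cycle (0.00307, and 0.365 with an estimated correlation) and oxidative phosphorylation (0.0123, and 0.244 with an estimated correlation) rose in cluster 6 with 0 called. Outside the lists, Zbp1, a nucleic acid sensor, fell by 1.35 ± 0.08 in cluster 5 and 1.46 ± 0.08 in cluster 6, and Cth, an enzyme of cysteine synthesis, rose in cluster 6 (1.12 ± 0.05). Called genes numbered 173 (30 higher) and 259 (33 higher). In cluster 5, 7 of 122 calls were higher with DESeq2 and 86 of 252 with doublets kept. In cluster 6, 17 of 192 were higher with DESeq2 and 64 of 380 with at least 500 genes per cell. Lower calls were the majority in each of these.

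Cluster 1 was higher in Csf3 and also in Csf2, at 13.5 ± 0.106 against 2.92 ± 0.171 CPM, and in the chemokine receptor Cxcr4 (3.22 ± 0.40). These were 3 of 8 colony-stimulating factors and receptors, a list not called by camera (adjusted p = 0.147). Hypoxia and glycolysis genes rose in 4 of 19, such as Ndrg1 (2.42 ± 0.08; 1.96e-11, and 0.139 with an estimated correlation). Dissociation stress genes rose in 6 of 15, such as the heat shock genes Hspa1a (4.0 ± 0.28) and Hspa1b (124 ± 33.1 against 19.5 ± 0.198 CPM; 3.16e-07, and 0.133 with an estimated correlation). The cluster also had fewer genes per cell, a median of 5024 against 6100 over all glioma-like cells. Its leading genes began with the immunoglobulin gene Igkc, of whose 3394 UMIs in the cluster 3393 lay in 1 cell. Myeloid suppression rose in 3 of 9: Ptgs2 (2.32 ± 0.08), Ptges and the heme oxygenase Hmox1 (2.18 ± 0.16; 0.000676, and 0.133 with an estimated correlation). Astrocyte-like genes rose in 3 of 7, such as the metallothioneins Mt1 (1.75 ± 0.07) and Mt2 (1.63 ± 0.08), and Hopx fell (0.00319, and 0.133 with an estimated correlation). Interferon genes fell in 12 of 20, such as Gbp2 (-1.95 ± 0.11; 6.67e-08, and 0.139 with an estimated correlation). MHC class I genes fell in 5 of 13, such as Psmb10 (-1.51 ± 0.10; 6.82e-05, and 0.243 with an estimated correlation), and cell cycle genes in 2 of 20, Ccnb2 and Rrm2 (6.88e-06, and 0.252 with an estimated correlation). Oxidative phosphorylation fell (0.0043, and 0.243 with an estimated correlation) and mesenchymal-like genes rose (0.0246, and 0.243 with an estimated correlation) with 0 genes called. In lists not called, the vascular growth factor Vegfa (1.45 ± 0.05), Tet2, a DNA demethylation enzyme (1.27 ± 0.12), and Idh1 (123 ± 3.20 against 68.2 ± 0.375 CPM, 1.08 ± 0.09) rose. Of 880 called genes 521 were higher, and 1424 were called with at least 500 genes per cell. Dusp4 (2.21 ± 0.11) and the keratin Krt19 (2.19 ± 0.13) rose and Irgm1 (-1.85 ± 0.09) and Pcolce (-1.49 ± 0.08) fell the furthest outside the lists, features and markers.

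Cluster 8 was led by Igfbp7, Timp3 and Scx, a tendon transcription factor that rose by 1.79 ± 0.06 (edgeR adjusted p = 1.53e-13). Its levels were 80.9 ± 4.22 against 27.6 ± 2.29 CPM. Angiogenesis genes rose with 1 of 16 called, the vessel growth factor Angpt1 (1.82 ± 0.35; list 0.0245, and 0.423 with an estimated correlation). Cell cycle (0.0025, and 0.712 with an estimated correlation) and dissociation stress (0.0333, and 0.712 with an estimated correlation) fell with 0 genes called. Csf2 rose (1.27 ± 0.28; 6.35 ± 3.85 against 4.11 ± 0.452 CPM), but the call was lost with at least 500 genes per cell. The libraries disagreed: Csf2 was at 3.63 CPM in replicate 1 and 9.07 in replicate 2, and the log2 change was 0.22 without replicate 2 and 2.15 without replicate 1. Of 260 called genes 201 were higher; DESeq2 called 149, doublets kept gave 475 and at least 500 genes per cell gave 165. Lists not named for a cluster were not called in it. Their adjusted p values started at 0.102 in cluster 1, 0.061 in cluster 18, 0.105 in cluster 5, 0.103 in cluster 6, 0.102 in cluster 7, 0.0765 in cluster 8 and 0.066 in cluster 9. Among these, median, mean and test differed in sign for myeloid suppression (clusters 18, 7, 8 and 9), reactive oxygen machinery (1 and 18), p53 response (1), astrocyte-like (18, 7 and 8), neural-progenitor-like (18, 5 and 8), methylation enzymes (18, 7 and 8), T cell exhaustion (5), angiogenesis (7 and 9), dissociation stress (7), MHC class I, hypoxia and mesenchymal-like genes (8) and colony-stimulating factors and receptors (9). Adjusted over the list alone, the counts in the 7 clusters differed in 14 cases, each by 1 gene except MHC class II in clusters 6 and 7, with 7 and 4 falls.

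Of the planned comparisons, early against mature neutrophil-like cells and T-like against NK-like cells were not made. Among the 22 and 20 neutrophil-like cells, 4 and 3 held a UMI of the granule genes Ngp, Camp or Ltf. Among the 42 and 38 T-like cells, 13 and 8 held a UMI of an NK marker. Both were fewer than the 20 cells per library that a class needed. The libraries differed in summed counts by more than sampling noise in glioma-like cells (chi-square per degree of freedom, 5.65; highest of 100 random deals of the cells, 3.26) and over all cells (7.19 against 6.09). In each other class they lay inside the range of random deals (permutation test; the smallest p that 100 deals can give is 0.0099).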

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

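The tests of reads shared with Hras, of few cells holding the Nras counts, of depth for Xist and both tests of depth for Csf3 were chosen after the results they measure were seen; the other 3 tests were not. The design has 1 group, so no biological explanation was tested.

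Signals stood above the limit of a count of 0 in cells and barcodes that no comparison used in the main setting. In unnamed cluster 12, which lay outside the glioma-like class, Nras was at 2366 ± 220 CPM (SD, n = 2 libraries; 10720 counts) and Csf3 at 2.65 ± 0.194 (12 counts), against a limit of 0.660 CPM. In unnamed cluster 15, led by oligodendrocyte and haemoglobin genes, Nras was at 2467 ± 659 CPM (3267 counts) and Csf3 at 10.2 ± 10.6 (12 counts), against a limit of 2.32 CPM. That Csf3 level rests on replicate 1, with 10 counts (17.7 CPM) against 2 in replicate 2 (2.74 CPM), which lie under the 3 counts of the limit. In the barcodes removed for few genes or a high mitochondrial share, the haemoglobin gene Hbb-bs made up 378586 CPM of the non-mitochondrial UMIs of replicate 1 (470430 counts) and 409513 CPM of those of replicate 2 (472627 counts).

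Nras was high in glioma-like cells, 22.6-fold over the 4 myeloid classes pooled. The fold of the related gene Hras was 2.21, just under the bound set for it after the values were seen. That does not decide on reads shared with Hras: reads that align to both genes are not counted, and misplaced reads need not raise Hras. A few extreme cells as the source were argued against, since 93.7% of the 1898 glioma-like cells stood above 1000 CPM. Whether the Nras counts of the host classes came from free tumour RNA stayed open: in cluster 0 the shares of the glioma-like level spread 4.73-fold over 5 tumour genes, but the top of that range is a floor of 3 counts set for Sox2, so it is no measured spread. There were 236 Nras counts, 25 of Cdkn2a where 30.8 would go with the Nras share, 4 of Nes where 9.16 would, 1 of Tnc and 0 of Sox2. An Nras gene brought into the tumour cells when the model was made is a candidate explanation of the glioma-like level, but the labels name no such gene and the counts cannot tell copies apart.

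Xist was scarce in glioma-like cells and abundant in host classes, while the Y chromosome genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in every class. Lower depth was argued against: the median UMIs per cell of glioma-like cells were 4.45 times those of cluster 0, while 1.84% of the former and 98.2% of the latter held a Xist UMI. Of the 35 glioma-like cells with a Xist UMI, 14.3% (exact 95% interval 4.81 to 30.3) held Tyrobp, Fcer1g or Ptprc. Of the other 1863, 9.29% did (Fisher exact test over cells, p = 0.371). This argues against doublets with immune cells that express these genes as the source of most of the 35 cells. It leaves open a smaller part, since the interval reaches well above 9.29%, and doublets with host cells that lack these genes. The cells with most Xist UMIs were not tested on their own. Of the 496 Xist UMIs, 423 lay in 15 cells of cluster 9. Loss or silencing of Xist in tumour cells of female origin may be weighed as a hypothesis, and it was not tested.

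Csf3 had 850 counts in glioma-like cells and 0 in the 4 myeloid classes. Lower depth of those classes together was argued against, since at the glioma-like level of 8.26 CPM their 6099549 UMIs would hold 50.4 counts. For neutrophil-like cells on their own it stayed open, since their 136602 UMIs would hold 1.13 counts. Whether few cells drove the glioma-like level stayed open too: the 10 cells with most Csf3 UMIs held 28% of them, which lay between the bounds set beforehand for and against it, and 316 cells held at least 1.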

How the results depend on the processing

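Counting cluster 12 as glioma-like and leaving out barcodes without a Malat1 UMI were chosen after the data were seen. With 2 libraries a value without one of them lies within 1 SD of the mean by construction, so leaving out a library says nothing about the shares, and counts of called genes have no such value for lack of residual degrees of freedom. Comparisons of glioma-like clusters could not be made with at most 10% mitochondrial UMIs, at resolution 0.5 or with list genes as features, where other numbers of clusters formed. Depth limits neutrophil-like cells most. Of 3046 values of named genes under other settings, 2911 kept direction and side of the threshold or stayed uncalled with either sign. Another 122 lost the call, 2 gained it (Csf3 in cluster 6) and 11 changed sign. Most losses came with DESeq2 (26), doublets kept (26) and resolution 2 (25), and none without a low-count filter. Keeping doublets added only 11 and 3 barcodes but clustered all cells anew. With one library, 591 of 596 kept their sign or were of genes not called, whose sign was not followed.

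Unless stated, the cause was not tested. Shares (percent) moved as follows. Without Malat1-free barcodes, by construction: T-like 2.69, dendritic-like 3.65, glioma-like 63.3, macrophage-like 2.39, monocyte-like 2.99, neutrophil-like 1.41, unnamed 7.70. With cluster 12 as glioma-like, by construction: glioma-like 64.3, unnamed 4.31. With doublets kept: dendritic-like 3.55, glioma-like 64.1, macrophage-like 5.40, unnamed 4.38. Only 11 and 3 barcodes were added there. Shifts of the glioma-like, macrophage-like and unnamed shares of that size need the new clustering or naming of cells. With at least 500 genes per cell: dendritic-like 3.52, glioma-like 61.9, macrophage-like 5.11, neutrophil-like 1.22, unnamed 6.65. With at most 10% mitochondrial UMIs: dendritic-like 3.51, glioma-like 65.2, macrophage-like 5.02, unnamed 3.92. At resolution 0.5: dendritic-like 2.20, glioma-like 65.7, macrophage-like 5.31, monocyte-like 4.07, unnamed 2.88. At resolution 2: cluster 0 10.8, macrophage-like 4.77, monocyte-like 2.38. With list genes as features: glioma-like 55.1, macrophage-like 5.37, unnamed 13.5.

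Counts of called genes left the range of 1.5 times with DESeq2 (149 in cluster 8, 154 in cluster 9), doublets kept (174 in cluster 7, 475 in cluster 8), at least 500 genes per cell (1424 in cluster 1, 136 in cluster 7, 165 in cluster 8) and resolution 2 (436 in cluster 9). With an estimated correlation, called lists fell to 4 of 14 for glioma-like, 0 of 5 for neutrophil-like, 1 of 10 for cluster 0, 2 of 8 for dendritic-like and 1 of 3 for mast cell or basophil-like cells, and for clusters 1, 18, 5, 6, 7, 8 and 9 to 0, 3, 1, 1, 2, 0 and 0.

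Log2 values that changed sign were Rsad2 in cluster 0 (0.26 with at least 500 genes per cell and with at most 10% mitochondrial UMIs, 0.38 and 0.10 at resolution 0.5 and 2, 0.32 with list genes as features), Cd74 in cluster 7 (0.32 at resolution 2), Hspa1a and Hspa1b in cluster 7 (-3.65 and -1.51 with doublets kept), Adm in cluster 8 (-3.70 with at least 500 genes) and Rsad2 in cluster 9 (0.54 with doublets kept, 0.99 with at least 500 genes). With one library, Mcm6 in mast cell or basophil-like cells ran from -0.27 to 2.36, Adm from -0.15 to 4.88 in cluster 1 and from -1.07 to 4.28 in cluster 8, Csf2 in cluster 8 from 0.22 to 2.15, Ciita in cluster 9 from 0.94 to 3.28, and Ccl6 from -0.0575 to 4.15 in cluster 8 and from -0.0848 to 3.67 in cluster 9.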

Other observations

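The comparison of mast cell or basophil-like cells and the leaving out of barcodes without a Malat1 UMI were chosen after the data were seen, as were the genes whose levels are given here.

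Levels of single cytokine genes in the mast cell or basophil-like class follow; the fixed cytokine list was not called in it. Of its 170 cells, 160 were in basophil-like cluster 2 and the other 10 held mast cell proteases such as Mcpt2 and Cma1, and the levels below are of the whole class. Il4, a cytokine of type 2 immunity, was at 1291 ± 590 CPM (SD, n = 2) and Il13 at 99.5 ± 45.5. The chemokines Ccl3 and Ccl4, which attract monocytes and T cells, were at 12677 ± 34.1 and 18870 ± 3675 CPM, and Osm, a cytokine of the interleukin 6 family, at 2727 ± 501. Of colony-stimulating factors and receptors 6 of 10 rose against the 4 myeloid classes, among them Csf1 (651 ± 44.0 CPM), the receptor subunit Csf2rb (1838 ± 426 CPM) and Kit (7.27 ± 0.99), and 3 fell, though the list was not called (adjusted p = 0.302 by camera of limma). Csf3r had 2 counts in the class, a ratio of 0.0213 to the pooled counts of the myeloid classes (counting interval 0.00257 to 0.0770). The protease gene Gzmb rose (2879 ± 224 against 2.76 ± 3.71 CPM) and Cd200r1, an inhibitory receptor of the checkpoint list, did too (4.01 ± 0.33), with 3 rising and 3 falling in that list (adjusted p = 0.745).

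Dissociation stress genes rose in 13 of 15 and fell in 1 in this class, with the heat shock gene Hspa1b at 296 ± 96.5 against 8.07 ± 3.21 CPM (list adjusted p = 6.68e-10, and 0.0478 with an estimated correlation). MHC class II genes fell in 5 of 11, such as Ctss (-3.53 ± 0.46; 0.000403, and 0.314 with an estimated correlation; 6 adjusted over the list alone), and astrocyte-like genes in 5 of 6 (0.00566, and 0.124 with an estimated correlation). No other list was called, with adjusted p values from 0.0501 for angiogenesis to 0.82 for cytokines, of which 8 rose and 8 fell of 23. Outside the lists the transcription factor Klf5 (7.17 ± 0.44) and the amino acid transporter Slc7a5 (6.70 ± 0.43) rose and Ifi211 was at least 24.4-fold lower. In all, 1825 of 8213 genes were called, 1215 higher and 610 lower around a median of 0.24. With RLE size factors the median was 0.06, with 991 higher and 738 lower. With DESeq2 it was -0.12, with 1020 higher and 907 lower, so the excess of higher genes rests in part on the scaling and the test.

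The T-like class, in which 13 of 42 and 8 of 38 cells held a UMI of an NK marker, had counts of killer cell genes and of inhibitory receptors, and summed counts do not show whether the same cells held both. Gzma was at 2526 ± 1742 CPM, Gzmb at 1673 ± 990, Prf1, which encodes perforin, at 224 ± 177 and Ifng at 126 ± 61.5. Pdcd1, which encodes PD-1, was at 326 ± 107 CPM, Ctla4 at 236 ± 207 and Lag3 at 159 ± 44.5. Cd8a (458 ± 77.9 CPM) stood above Cd4 (86.9 ± 41.6), and the regulatory T cell factor Foxp3 was at 64.0 ± 60.5, with SDs over the 2 libraries near the means for several of these genes. In the neutrophil-like class, Ngp, a granule gene of early cells, was at 13812 ± 8844 CPM, though only 4 of 22 and 3 of 20 cells held a UMI of Ngp, Camp or Ltf. Retnlg, a gene of mature neutrophils, was at 5455 ± 965, and Cd274, which encodes PD-L1, was at 433 ± 182.

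Unnamed cluster 12 (144 cells) joined tumour and mural or fibroblast features. Pdgfrb, a receptor of mural cells and fibroblasts, was at 135 ± 30.7 CPM against 10.7 ± 1.67 in glioma-like cells and the collagen gene Col1a1 at 19.5 ± 13.2 against 0.216. Its Sox2 (21.0 ± 2.47 CPM), Tnc (108 ± 17.9), Cdkn2a (739 ± 62.2) and Trp53 (11.7 ± 3.49) levels lay on the glioma-like side, as did Xist (21.5 ± 14.6). Counted as glioma-like, it would bring the glioma-like share to 64.3%.

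Barcodes without a Malat1 UMI made up 126 of the 199 macrophage-like barcodes and held 1 Neat1 UMI, another nuclear RNA, where the 73 others held 249. Hbb-bs was at 2598 CPM in them against 12.9, and the complement gene C1qa at 14060 against 10389 CPM. In the 38 such barcodes of cluster 15, Hbb-bs was at 51363 against 5191 CPM. Parts of cells without a nucleus may be a candidate explanation, for which no test was made; left out, they bring the macrophage-like share to 2.39%.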
